A study of Mus musculus with 8 samples.

How the data were processed

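RNA was measured in 8 samples of sorted primordial germ cells at embryonic day 11.5, with 4 Control and 4 Prmt5 KO libraries. Per the labels' protocols, RNA was extracted with a PicoPure kit and each library was prepared from 50 pg of total RNA with a published single-cell method. The files the authors deposited hold whole-number read counts, 1 value per transcript and library, and list only transcripts with a count of at least 1. The submitters' processing notes name the builds GRCm38 and mm10; the aligner, the counter, the annotation release and the strand setting are not given in the sources used here. The design was written for gene counts, before the data were examined, and the files turned out to hold transcript counts, so a gene value had to be built.

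Transcript identifiers were matched to GENCODE release M21 on GRCm38: 64258 of 66262 identifiers (97.0%) matched, giving 21444 genes. The 2004 unmatched identifiers held between 1.75% and 1.90% of the counts of a library and were left out. Reads that overlap several transcripts of a gene appear to be counted for each of them: of 6532 genes with at least 2 transcripts of 100 or more counts, 1132 had transcripts with identical counts in all 8 libraries. Adding transcripts would then count reads repeatedly, so the value of a gene was the count of its transcript with the highest total over the 8 libraries, chosen without regard to group. These values made up 43.7% of the summed transcript counts. Pseudogenes held 3.70% of the gene counts, most of it on Gm6754, a processed pseudogene with 3.23%, so reads shared between pseudogenes and parent genes are uncertain.

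Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 10990. Libraries were scaled by TMM, and Prmt5 KO was compared with Control in all 8 libraries with edgeR's quasi-likelihood test (robust estimation) and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM were computed on the TMM-scaled library sizes. The 19 gene lists were fixed with the design; those with at least 4 tested members were tested with camera (correlation 0.01), camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Single values were compared by two-sided exact permutation over the 70 assignments of libraries, whose smallest p is 0.0286. The ratios of Prmt5 transcripts and the estimated correlation in the alternative fits were added after results were seen. No libraries were duplicates of each other.

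Genes named were Prmt5; per direction up to 10 genes with the smallest adjusted p among those past 0.05 whose 4 Prmt5 KO libraries lay on the same side of the Control mean, or, where fewer than 5 qualified, the 5 with the smallest unadjusted p, passing over clone names; from each list the called members (at most 4) or else the 2 with the smallest unadjusted p; and the most abundant marker of each other cell type. Any other gene named was chosen after its values were seen.

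The gene test was checked on simulated counts with the means and library sizes of the 10990 genes in this comparison. The spread of each gene was the one edgeR estimated, and no library was set apart, so the rates need not hold for the real libraries. Genes were simulated independently, and the changed ones were drawn only from genes above a set mean CPM, so the rates do not cover scarcer genes. edgeR called 24% of genes changed 2-fold and 71% of those changed 4-fold, and 4 of 10537 unchanged genes. DESeq2 called 37% and 80%, and 27 unchanged genes, so a larger share of its calls was false than in edgeR. A gene that changed 2-fold was thus more often missed than called at this depth and spread (common biological coefficient of variation 0.488). Alternatives covered the scaling, the tool, the filter, robust estimation, the replicate block, left-out genes and libraries, covariates, the gene value and depth. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9. Transposon transcripts were not analysed here.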

Results

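Primordial germ cells, the embryonic precursors of sperm and eggs, were profiled by RNA sequencing in mouse embryos at embryonic day 11.5. Cells carrying a germ cell reporter, green fluorescent protein under a piece of the Oct4 promoter, were taken by flow sorting. The 4 Control libraries came from embryos with Cre recombinase under Blimp1 and 1 floxed copy of Prmt5, and the 4 Prmt5 KO libraries from embryos with Cre and both copies floxed. Prmt5 encodes the arginine methyltransferase that makes symmetric dimethylarginine on histones and splicing proteins. Each library was made from 50 pg of total RNA and sequenced on a SOLiD instrument. The total of the gene counts was 5844437, 2289231, 1811433 and 5583565 in Control 1 to 4, and 6116069, 5058485, 6549498 and 4318974 in Prmt5 KO 1 to 4. Between 14398 and 17427 genes had at least 1 count in a library. The labels do not say whether the 4 libraries of a group came from separate embryos or litters, so every p-value measures the spread between these libraries, which may be partly technical.

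The targeted gene was examined in every library first. Prmt5 (ENSMUSG00000023110, GRCm38 chromosome 14, 54507187 to 54517525, minus strand) was at 89.4, 171, 172 and 118 CPM (counts scaled to library size) in Control 1 to 4 and at 39.9, 40.5, 35.3 and 26.4 in Prmt5 KO 1 to 4. Its level fell from 138 ± 40.6 CPM in Control to 35.5 ± 6.49 CPM in Prmt5 KO (SD, n = 4 each). This is a log2 fold change of -1.95 with a standard error of 0.272 and an adjusted p of 0.0388 (edgeR quasi-likelihood test). No Prmt5 KO library reached the level of any Control library. The call was lost on leaving out any library except Control 1, with an adjusted p between 0.0578 and 0.233, while the log2 fold change stayed between -1.82 and -2.01. The 6 shorter annotated Prmt5 transcripts were at lower shares of their Control means than the full transcript of 17 exons (25.8%), from 19.9% for the one spanning exons 1 to 6 down to 12.5% for exons 1 to 11 and 11.6% for exons 7 to 12. As a percent of the full transcript's counts, the transcript of exons 7 to 12 was at 20.8 ± 2.27 in Control and 9.55 ± 3.64 in Prmt5 KO, and that of exons 1 to 11 at 24.5 ± 1.91 and 11.7 ± 5.61 (SD, n = 4 each). For these ratios the groups did not overlap, but the lowest adjusted p over the 6 ratios was 0.0857 (two-sided exact permutation). None could pass unless at least 4 were separated, so this does not show that the ratios were alike. These transcripts share reads, and the loss is not placed in particular exons. Which exons were floxed is not given in the sources used here.

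**Figure D1:**
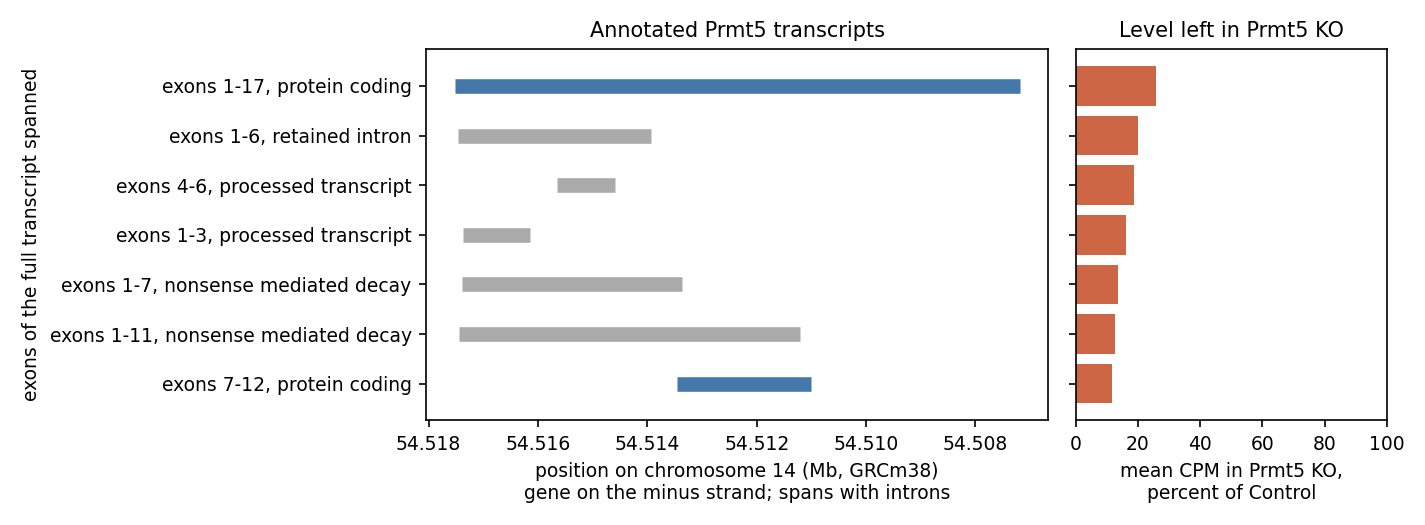
Left, the 7 annotated Prmt5 transcripts with counts, each drawn from its start to its end on chromosome 14 (GRCm38, megabases), protein-coding ones in blue and others in grey. Right, the mean CPM of each transcript in Prmt5 KO as a percent of its Control mean (n = 4 libraries per group), from 25.8% for the full transcript down to 11.6% for the one spanning exons 7 to 12.

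The comparison asks which genes differ at embryonic day 11.5, in the period of global DNA demethylation, between germ cells of the Prmt5 KO and Control genotypes. Both carry Cre, and the Control has 1 floxed copy of Prmt5. Beside the fall of Prmt5, 2 genes rose, and both are classical targets of the p53 tumour suppressor. Ccng1, which encodes cyclin G1, rose 3.92-fold, from 55.7 ± 9.09 to 219 ± 22.8 CPM (SD, n = 4 each; log2 fold change 1.97, standard error 0.195, edgeR adjusted p = 0.00137). Mdm2, which encodes the ubiquitin ligase that holds p53 in check, rose 2.12-fold, from 120 ± 13.5 to 254 ± 24.3 CPM (SD, n = 4 each; log2 fold change 1.09, standard error 0.163, edgeR adjusted p = 0.0490). Each rise was seen in all 4 Prmt5 KO libraries. These 3 genes were all that passed an adjusted p of 0.05 among 10990 tested; 896 genes had an unadjusted p under 0.05, of which 491 were higher and 405 lower, against 549.5 by chance. The Ccng1 call held on leaving out each library in turn. The Mdm2 call was lost on leaving out any of the 8 libraries, with an adjusted p between 0.0578 and 0.262 and a log2 fold change between 1.03 and 1.16. Without Control 2 and 3, the shallowest libraries, no gene passed in edgeR and 713 genes had an unadjusted p under 0.05. DESeq2, run on all 8 libraries, called 107 genes, 62 higher and 45 lower. On simulated counts DESeq2 called 27 unchanged genes against 4 in edgeR, so part of these 107 may be false calls.

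The next genes by unadjusted p missed the threshold in edgeR. Higher in Prmt5 KO were Eda2r, a death receptor of the tumour necrosis factor family (log2 fold change 2.29, adjusted p = 0.121), Arhgap23 (3.60, adjusted p = 0.121) and Ass1, an enzyme of arginine synthesis (1.36, adjusted p = 0.147). Lower were Cdk10, a cyclin-dependent kinase (-2.32, adjusted p = 0.121), Yif1a (-2.54, adjusted p = 0.147), Xrcc6, which encodes the Ku70 protein of DNA end joining (-0.85, adjusted p = 0.159), and Spata24 (-3.75, adjusted p = 0.164). All 7 passed in DESeq2, Eda2r, Arhgap23 and Cdk10 also in edgeR with no filter, and Eda2r and Ass1 in limma voom. A call by DESeq2 alone was taken as weaker, as DESeq2 made more false calls on simulated counts, though these used the spread edgeR estimated. For each of these genes all 4 Prmt5 KO libraries lay on the same side of the Control mean. Spata24 was scarce, at 7.93 ± 3.27 CPM in Control and 0.568 ± 0.284 in Prmt5 KO (SD, n = 4 each). Exons of Xrcc6 overlap those of Desi1 on the opposite strand, and those of Yif1a overlap Cnih2, so their counts are uncertain as the strand used in counting is not given.

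**Figure D2:**
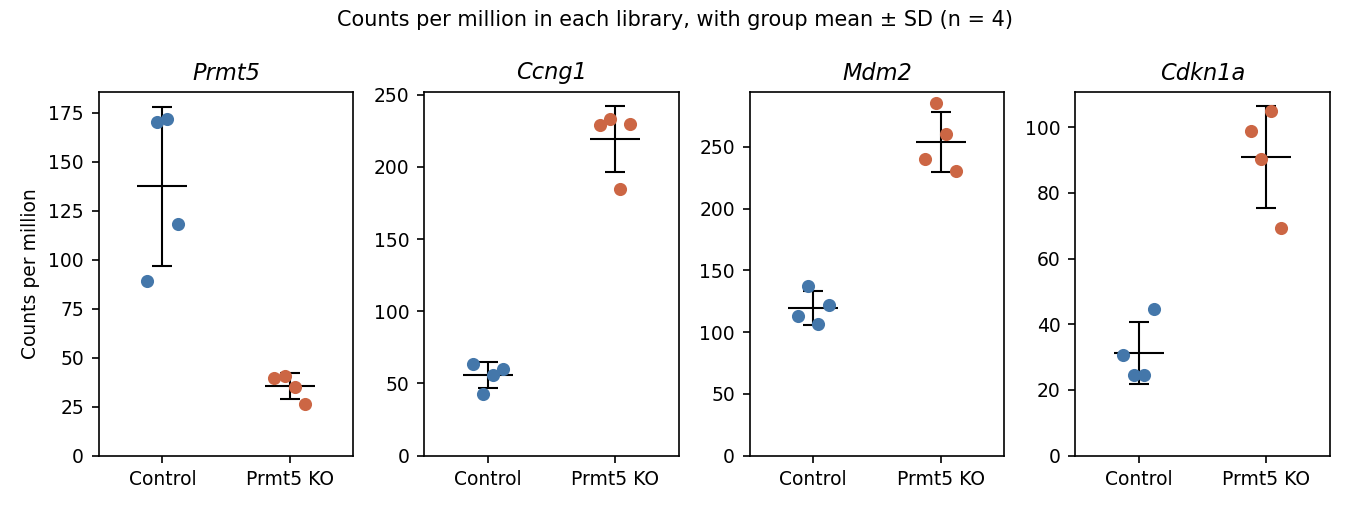
CPM (linear axes from 0) of Prmt5, Ccng1, Mdm2 and Cdkn1a in each library, with points for the 4 Control and 4 Prmt5 KO libraries and bars for the group mean ± SD. Ccng1 averaged 55.7 CPM in Control and 219 in Prmt5 KO, and the groups did not overlap for any of these genes.

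The p53 target genes rose together. Of 35 tested members of the 39 on the list, 31 had a log2 fold change above 0, with a median of 0.80. Over all genes 2 members were called higher, 0 lower and 33 did not pass; DESeq2 called 11 members, limma voom 4 and edgeR with no filter 3. Adjusted over the list alone in edgeR, 16 rose and 0 fell. Among those 16, named after their values were seen, were Cdkn1a, the p21 inhibitor of the cell cycle, from 31.1 ± 9.46 to 90.9 ± 15.6 CPM (SD, n = 4 each), and Phlda3, a repressor of Akt signalling, with a log2 fold change of 2.32. It was the only list of the 17 tested to pass in camera (adjusted p = 1.68e-21, with a preset correlation between genes of 0.01). With an estimated correlation its call held (adjusted p = 0.000469), and it also passed in fry (adjusted p = 5.94e-05). The list kept an adjusted p of at most 6.27e-08 at the preset correlation under every alternative fit, and of at most 0.0303 with an estimated correlation in the 22 alternative edgeR fits. Trp53 itself had a log2 fold change of 0.27 (adjusted p = 0.750 in edgeR).

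**Figure D3:**
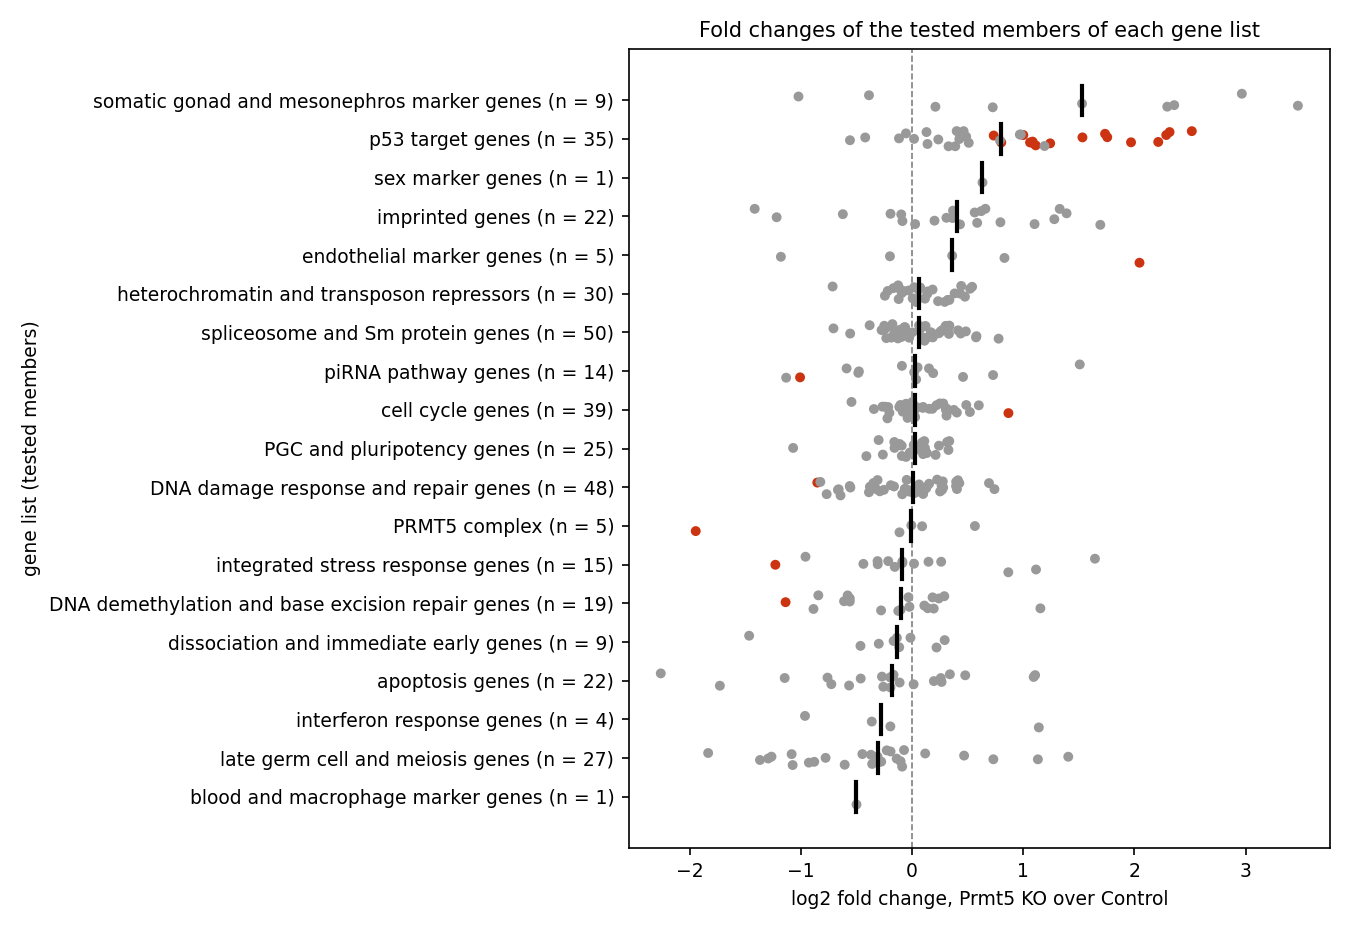
Log2 fold change of Prmt5 KO over Control for the tested members of each of the 19 gene lists (1 point per gene; vertical bars mark list medians). Red points passed when adjusted over the list alone; they number 16 in the p53 list, whose median is 0.80.

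Germ cell identity genes did not pass as groups. Of 25 tested genes of primordial germ cells and pluripotency, 0 were called and 0 passed adjusted over the list alone, with a median log2 fold change of 0.02; Tdgf1, a Nodal co-receptor, was at -1.07 and Utf1, a chromatin factor of pluripotent cells, at 0.33. Of 14 tested genes of the piRNA pathway, which silences transposons in germ cells, 0 were called over all genes and 1 fell adjusted over the list alone, Tdrkh (log2 fold change -1.01); Pld6 was at -1.13. Of 27 tested genes of later germ cells and meiosis, 0 were called over all genes or adjusted over the list alone, but 22 had a log2 fold change below 0, with a median of -0.31 and an adjusted p of 0.186 in camera. Among them Syce2, of the synaptonemal complex, went from 181 ± 36.1 to 94.9 ± 27.8 CPM (SD, n = 4 each) and Dmc1, the meiotic recombinase, from 18.5 ± 14.3 to 5.17 ± 2.65. In camera at the preset correlation that list passed in DESeq2 (adjusted p = 0.0423) and with genes detected as a covariate (0.0469), and also without Control 2 (median -0.49, 0.00116), without Prmt5 KO 4 (-0.57, 0.0118), without Control 2 and 3 (-0.59, 5.82e-05) and without Prmt5 KO 1 and 4 (-0.72, 0.0117), while its median was 0.0078 without Control 1. With an estimated correlation it did not pass in the fit on all libraries (adjusted p = 0.594) or in any of the 5 edgeR fits among these (adjusted p from 0.329 to 0.626), nor did it in fry (0.474).

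Genes of DNA repair and chromatin also did not pass as groups. Among 48 tested genes of the DNA damage response, 0 were called over all genes and 1 fell adjusted over the list alone, Xrcc6 (247 ± 33.2 to 137 ± 9.83 CPM, SD, n = 4 each); Ruvbl1 was at a log2 fold change of 0.40. Of 19 tested genes of DNA demethylation and base excision repair, 0 were called over all genes and 1 fell adjusted over the list alone, the DNA ligase gene Lig3 (117 ± 18.3 to 53.1 ± 12.5 CPM, SD, n = 4 each); Dnmt1, the maintenance DNA methyltransferase, was at 0.29. Exons of Lig3 overlap those of Rffl on the opposite strand, and those of Sf3b3, Wdr77 and Riok1, named below, overlap Cog4, Atp5f1 and Cage1, so their values are uncertain. Of 30 tested heterochromatin and transposon repressor genes, 0 passed by either adjustment, with Cbx1 at -0.71 and Mga at 0.54. Of the 5 genes of the PRMT5 complex, Prmt5 fell and the other 4, with Wdr77 at a log2 fold change of -0.01 and Riok1 at 0.57, did not pass by either adjustment. Of 50 tested spliceosome and Sm protein genes, which include substrates of PRMT5, 0 passed by either adjustment; Srsf1 was at 0.44 and Sf3b3 at 0.48.

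Cell cycle, death and stress genes gave few calls. Among 39 tested cell cycle genes, 0 were called over all genes and 1 rose adjusted over the list alone, Kif11, a motor of the mitotic spindle (110 ± 14.6 to 200.5 ± 43.3 CPM, SD, n = 4 each); Nusap1 was at a log2 fold change of 0.52. Of 22 tested apoptosis genes, 0 passed by either adjustment, with Diablo at -1.15 and Casp8 at -2.26. Casp8 was scarce, at 6.12 ± 4.41 CPM in Control and 1.21 ± 1.15 in Prmt5 KO (SD, n = 4 each), and its groups overlapped. The cell death genes Bax, Bbc3, Pmaip1, Apaf1, Perp and Aen were in the p53 list and not counted here. Their log2 fold changes ran from -0.05 for Pmaip1 to 1.19 for Apaf1. Perp (1.06) and Aen (0.80) rose adjusted over the p53 list alone, and the others of these did not pass. The apoptosis list had a median of -0.18 and was called lower by fry (adjusted p = 0.0383) but not by camera (adjusted p = 0.186, or 0.511 with an estimated correlation). Of 15 tested genes of the integrated stress response, 0 were called over all genes and 1 fell adjusted over the list alone, Mthfd2, a mitochondrial folate enzyme (log2 fold change -1.23); Ppp1r15a was at 1.65. Of 4 tested interferon response genes, 0 passed by either adjustment (Bst2 at 1.14, Stat2 at -0.96). Of 22 tested imprinted genes, 0 passed by either adjustment, with a median of 0.40, Slc22a18 at -1.42 and Gnas at 0.59. Exons of Nusap1, Diablo and Gnas overlap those of Oip5, B3gnt4 and Gm20721 on the opposite strand, so these values are uncertain.

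Markers of other cells that a sort of embryonic gonads could hold were measured the same way. Of 9 tested markers of somatic gonad and mesonephros, 0 passed by either adjustment, with a median log2 fold change of 1.53 that came from Prmt5 KO 1: the smooth muscle actin gene Acta2 was at 208 CPM and the collagen gene Col1a1 at 92.9 CPM in that library. Without Prmt5 KO 1 the median was -0.22. Mfge8, the most abundant marker, was at 145 ± 27.2 CPM in Control and 167 ± 10.8 in Prmt5 KO (SD, n = 4 each). Of 5 tested endothelial markers, 0 were called over all genes and 1 rose adjusted over the list alone, Tek, the angiopoietin receptor (12.3 ± 11.2 to 52.3 ± 28.1 CPM, SD, n = 4 each), while Egfl7 was at a log2 fold change of -1.18. Csf1r, the 1 tested marker of blood and macrophages, was at 33.8 ± 9.42 and 23.7 ± 14.2 CPM (SD, n = 4 each). Exons of Csf1r overlap those of Hmgxb3, and those of Egfl7 overlap Agpat2 and Gm20532, so both are uncertain. Of 9 tested genes of dissociation stress, 0 passed by either adjustment (Klf4 at -1.47, Egr1 at -0.46). Of the sex markers 1 gene, Xist, was tested, at a log2 fold change of 0.63 that did not pass.

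The libraries were compared for quality. Total counts, genes detected, and the shares of counts on mitochondrial genes, ribosomal protein genes, haemoglobin genes and the 50 top genes gave an unadjusted p from 0.114 to 0.543 in two-sided exact permutation tests between the groups. With 6 measures a single separated one could reach an adjusted p of only 0.171, so these tests do not show that the groups were alike. Mitochondrial genes held 10.3% ± 0.761 of counts in Control and 9.66% ± 1.07 in Prmt5 KO (SD, n = 4 each). In multidimensional scaling, Prmt5 KO 4 lay at -2.69 on dimension 1, where the other libraries lay from 0.21 to 0.86, and Prmt5 KO 1 lay at -2.26 on dimension 2. The p53 list also passed without both of these libraries (median 0.76, camera adjusted p = 3.19e-19), and Ccng1 was then the 1 gene called.

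**Figure D4:**
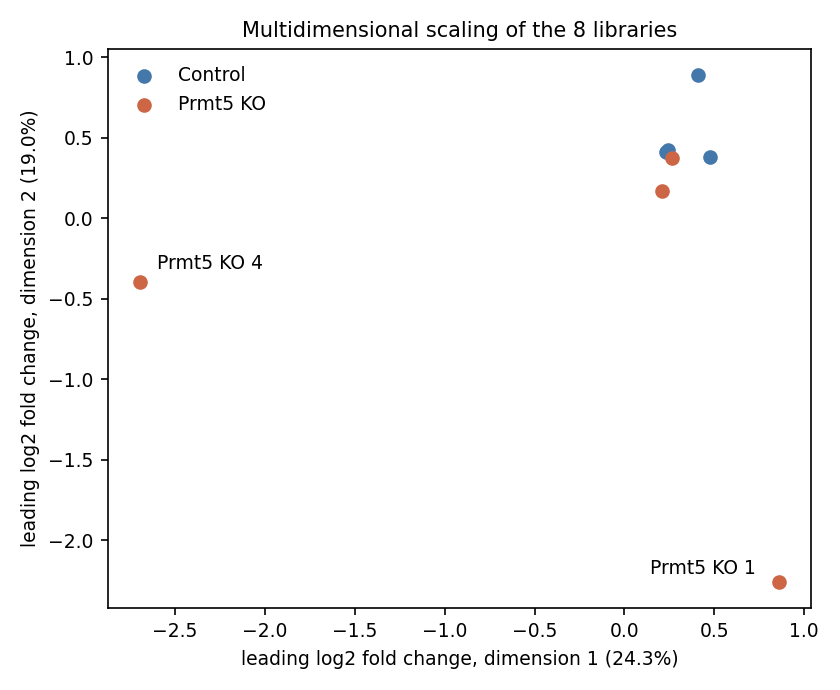
Multidimensional scaling of the 8 libraries on log2 CPM, with axes in leading log2 fold change; dimension 1 holds 24.3% and dimension 2 holds 19% of the variation. Prmt5 KO 4 (at -2.69 on dimension 1) and Prmt5 KO 1 (at -2.26 on dimension 2) lie apart from the other 6 libraries.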

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

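The tests that leave out Prmt5 KO 1, both tests of its somatic markers and the thinning test on shared members were chosen after the result was seen. Within each group of 4 libraries, 130 sets of values (named genes, list means and library quality) were searched for a library far from the other 3. This singled out 16, where chance would give about 1 in 20, or 6.5, for independent and normally distributed values. Named genes also enter the list means, so the sets are not independent and 6.5 is only a guide.

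Prmt5 KO 1 stood out for Acta2 (208 CPM), Col1a1 (92.9 CPM) and the mean of the somatic gonad list (5.68 log2 CPM). It was also set apart by a high mitochondrial share (11.3%), a low Syce2 (53.2 CPM), and low means of the germ cell and pluripotency list (7.08) and the heterochromatin list (6.48). Prmt5 KO 4 had a high Sf3b3 (1013 CPM), a low Diablo (17.2 CPM) and a low mean of the DNA damage list (5.80). Among the Prmt5 KO libraries, Ccng1 was lowest in Prmt5 KO 3 (185 CPM). Among the controls, Tdgf1 was low in Control 4 (19.3 CPM), Col1a1 was high in Control 2 (6.25 CPM), Tek was high in Control 1 (28.9 CPM), the demethylation and base excision repair list was high in Control 4 (5.65) and the cell cycle list was high in Control 1 (8.16).

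The mean of the p53 list was higher in each Prmt5 KO library (5.35 to 5.62 log2 CPM) than in every Control library (4.59 to 4.89). Of its 35 tested members, 4 had a log2 fold change below 0. Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave a camera p as small (real 9.87e-23, smallest of the others 1.58e-08). Only the real split called as many genes (real 3, highest of the others 0), and those 3 include Prmt5, the targeted gene. A share of 1 in 35 is under 0.05 and the smallest this design can give. Prmt5 was deleted by design, and its call alone would set the real split apart, as the others called 0. The number of genes therefore cannot decide on chance for the other genes called. The p53 list was 1 of 17 tested, and the splits did not compare the smallest p of any list. By themselves the splits therefore do not exclude chance for that list. Its p adjusted over the 17 lists argues against chance, if the libraries are independent. This adjusted p was 1.68e-21 in camera, 0.000469 in camera with an estimated correlation and 5.94e-05 in fry. Chance stays open for the number of lists called, since 27 of the 35 splits called 1 or more and another called 5. After thinning to equal depth the p53 median was 123% of its value, but fewer members were then tested. Over the 33 members tested both ways it was 102% (0.97 before and 0.98 after). Thinning keeps each gene's expected share of counts, so it cannot decide on a depth difference as the cause. Without Control 2 and 3, the shallowest libraries, the p53 median was 0.91 (camera adjusted p = 1.57e-16), which argues against their low depth as the cause. Markers of other cell types had a median log2 fold change of 0.73 with an upper 95% bound of 2.05, which leaves RNA from other cells open over all 8 libraries. With Prmt5 KO 1 left out the bound was 0.18, under the p53 median of 0.83. These bounds come from resampling the marker genes, which may vary together, and hold no spread between libraries. In Prmt5 KO 2 to 4 the markers of the 3 lists summed to 364, 385 and 316 CPM, within the 274 to 393 of Control. For those libraries this argues against more RNA from cells with these markers as the cause. RNA from other cells is not excluded for Prmt5 KO 1 or for cells without these markers. A p53 response to loss of Prmt5 in germ cells remains a hypothesis.

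The somatic signal in Prmt5 KO 1 was weighed against the genotype. Of 11 tested smooth muscle and mesenchyme genes outside the fixed lists, 7 were highest in Prmt5 KO 1, among them Actg2 at 101 CPM and Myl9 at 47.4 CPM. The other 4, Fn1, Lgals1, S100a6 and Igfbp3, were highest in another library. These genes were chosen after the signal was seen and vary together, so no p is given, and whether RNA from mesenchymal cells passed the reporter sort stays open for this library. A rise shared by all Prmt5 KO libraries was argued against, since the somatic list in Prmt5 KO 2 to 4 lay -0.29 log2 from Control (upper bound of 2 standard errors 0.086), against 2.42 in Prmt5 KO 1. An effect of the deletion in that library alone stays open.

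Prmt5 KO 4 lay apart in multidimensional scaling. Thinned to equal depth it had 13600 genes detected, against 14081 to 14906 in the other libraries, so a less complex library is a candidate explanation. Its markers of other cells summed to 316 CPM, within the 274 to 976 of the others, which argues against RNA from other cells. Its late germ cell list averaged 4.68 log2 CPM, within the 4.04 to 5.34 of the others. The Control libraries alone span that whole range, so this cannot decide on a different stage. Whether low complexity came from handling or from the cells was not tested.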

How the results depend on the processing

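The fits on summed or longest transcripts, thinned counts, without pseudogenes, without Control 2 and 3, and without Prmt5 KO 1 and 4 were chosen after seeing the data. Against 3 genes called (2 higher, 1 lower), DESeq2 called 107 (62 higher, 45 lower), limma voom 10 (7 and 3), and the fit with no filter 7 (5 and 2). Without robust estimation 1 gene was called higher, and after thinning 1 was. The fits with genes detected as a covariate, with summed transcripts and without Prmt5 KO 1 and 4 each called 1 gene, higher, and 0 lower. The fits with a Y-linked covariate and without Control 2 and 3 called 0 in edgeR, 0 higher and 0 lower, with 1260 and 713 genes at an unadjusted p under 0.05. The Y-linked genes had 1 to 3 counts per library, so that covariate is near void. Leaving out each library in turn gave 1 to 2 genes, 1 higher and 0 to 1 lower. Ccng1 was among the genes called in all of these fits but those with 0. Lists past the threshold numbered 3 in DESeq2, 2 with genes detected as a covariate, 2 without Control 2 and 3, 2 without Prmt5 KO 1 and 4, 2 in fry and 1 to 2 on leaving out 1 library, against 1. The lists added were late germ cell genes, except somatic gonad genes beside them in DESeq2, cell cycle genes without Control 1 and apoptosis genes in fry; none of those added in the edgeR fits by camera held with an estimated correlation (adjusted p from 0.329 to 0.626). The p53 list was called in every one of these fits, with a median log2 fold change from 0.74 to 1.04. The log2 fold change of Prmt5 missed the threshold with the Y-linked covariate (-1.72), genes detected (-1.74), summed transcripts (-2.25), without Control 2 and 3 (-1.54) and without Prmt5 KO 1 and 4 (-1.85), and ranged from -2.11 to -1.82 on leaving out 1 library. The Prmt5 call was kept without Control 1 (adjusted p = 0.0198), and the cause of the losses was not tested.

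Replicate numbers are shared between the groups, and the labels do not say whether equal numbers mark a shared litter or run. Samples with the same number correlated by 0.07, 0.04, 0.0016 and 0.05 in their deviations from the group means. For 3 of 4 numbers the sample correlated best with its own. Pairing is thus neither shown nor excluded, and the main comparison did not use it. With the replicate block 1 gene was called, 1 higher and 0 lower, and Prmt5 was at -1.92 (edgeR adjusted p = 0.130).

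The results that changed direction were not past the threshold in either direction, and the cause was not tested. Without Prmt5 KO 1 and 4 the log2 fold change was -0.20 for Acta2, -0.50 for Col1a1 and 0.044 for Csf1r, and the list medians were -0.12 for piRNA, -0.070 for DNA damage, 0.031 for integrated stress and -0.52 for somatic gonad genes. Without Control 2 and 3 the medians were 0.0060 for the PRMT5 complex, -0.29 for piRNA, -0.087 for DNA damage and 0.10 for dissociation genes. With no filter they were 0.025 for the PRMT5 complex, -0.068 for piRNA, 0.11 for integrated stress and -1.15 for endothelial genes. In limma voom they were -0.036 for germ cell and pluripotency, -2.29e-05 for piRNA and -0.068 for DNA damage genes. With the Y-linked covariate they were -0.067 for piRNA and -0.18 for DNA damage genes, and with genes detected -0.063 and -0.038. DNA damage genes were also at -0.0038 with the stricter filter, -0.065 with the replicate block and -0.013 after thinning. On leaving out 1 library, the values ranged from -0.25 to 3.88 for Acta2 and from -0.60 to 3.47 for Col1a1. List medians then ranged from -0.18 to 0.037 for DNA damage, -0.051 to 0.052 for germ cell and pluripotency, -0.061 to 0.040 for the PRMT5 complex, -0.0013 to 0.093 for cell cycle, -0.57 to 0.0078 for late germ cell, -0.21 to 0.22 for piRNA, -0.22 to 1.88 for somatic gonad and -0.026 to 0.15 for spliceosome genes. Of the comparisons of single genes and lists, 1266 kept direction and side of the threshold, 44 changed direction, 26 newly passed and 31 no longer passed, of which 16 were of Mdm2, 13 of Prmt5 and 2 of Ccng1. Tdrkh, Syce2, Lig3, Kif11, Mthfd2 and Tek passed over all genes in DESeq2 alone. No scaling moved the median of all genes by over 0.1 log2. At this depth, spread and number of libraries a 2-fold change was called in 24% of simulated genes, drawn from those above a set mean CPM. Which of depth, spread and number of libraries sets the limit was not tested.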

Other observations

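The genes named here were chosen after their values were seen, while the fits that gave those values were planned. The test of retained introns was set before its result was seen. Mdm4, the partner of Mdm2 in holding p53 in check, was at 13.4 ± 5.41 CPM in Control and 40.2 ± 11.6 in Prmt5 KO (SD, n = 4 each; log2 fold change 1.59, edgeR adjusted p = 0.292), without overlap of the groups. Ercc5, an endonuclease of nucleotide excision repair, was at 24.6 ± 14.8 and 103 ± 27.4 CPM (SD, n = 4 each; log2 fold change 2.07, edgeR adjusted p = 0.202). Lefty1, an inhibitor of Nodal signalling, was at 26.2 ± 12.7 and 84.6 ± 25.7 CPM (SD, n = 4 each), and Fgf5, a growth factor of the early epiblast, at 17.2 ± 6.17 and 4.81 ± 0.361 (SD, n = 4 each); neither passed in edgeR (adjusted p = 0.202 and 0.377). All 4 of these genes passed in DESeq2, and Ercc5 also in limma voom and in edgeR with no filter.

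PRMT5 methylates splicing proteins, so a rise of retained-intron transcripts was tested as a hypothesis. Over 3209 retained-intron transcripts of 1921 genes, the median log2 ratio to the main transcript, less that of other coding transcripts, was -2.20 ± 0.00213 in Control and -2.21 ± 0.0348 in Prmt5 KO (SD, n = 4 each). The difference was -0.018 (two-sided exact permutation p = 0.400). A rise was not seen, but reads shared between transcripts blunt this measure, and it cannot exclude changes in single introns.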
